A study of Xenopus laevis with 8 samples.

How the data were processed

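The arrays measured RNA from animal caps of Xenopus laevis in 4 groups of 2 samples, each on its own array with 32635 probe sets. The deposited values are linear signal intensity values, 1 per probe set and array; the MAS5 algorithm is named in the submitters' processing notes, and its version is not given in the sources used here. The 2% trimmed mean of every deposited array rounds to 500, so the values had been scaled array by array to a common mean, and no further normalization was applied in the main analysis. No intensity was 0 or below. Total RNA was extracted, amplified by in vitro transcription and labelled with biotin, per the labels' protocols. Groups and replicate numbers come from the sample labels, and no column of another series was present. The series text mentions both RNA extraction from caps cut at stage 9 and culture to stage 15 before collection for the arrays; the later stage is used here.

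The 96 manufacturer control probe sets were left out of all tests. Signals were transformed to log2(signal + 5.22), the pseudocount being the 10th percentile of all signals in the table. A probe set was kept when its signal exceeded the 40th percentile of its array on at least 2 arrays, which left 22000 of 32539. Limma 3.58.1 in R 4.3.3 was used (lmFit, and eBayes with trend and robust), with all 8 arrays in a single fit of group means and 4 residual degrees of freedom, so that the groups share an estimate of spread. The contrasts were chordin against uninjected, wnt3a added to chordin, the morpholino added to chordin and wnt3a, and chordin with wnt3a against uninjected. A probe set was called when its Benjamini-Hochberg adjusted p was below 0.05 within a contrast. Standard errors are those of the fitted log2 change with 2 arrays per group, and the median was 0.29. Those given for gene lists in the closing sections are instead taken over the genes of the list, which are not independent replicates. The labels do not say that replicates were separate batches of embryos, so the p-values measure only the spread between these samples, which may be technical. For arrays, their number limits the precision. The labels do not say what a shared replicate number marks. The replicate 1 minus 2 differences of the groups correlated at 0.172 to 0.505 in all 6 pairs of groups, and the 3' to 5' signal ratio of the gapdh controls was 1.26 to 1.41 on replicate 1 arrays and 1.61 to 1.76 on replicate 2 arrays. The numbers were therefore taken to pair the arrays, a decision made after counts with the block had been seen. Total counts and changed list calls with the replicate number as a block are given. Changed gene calls and member counts are given only in part. The main fit was fixed without the block.

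The files hold no detection calls. A background was therefore set for each array, after the values were seen, as the highest signal of 23 negative control probe sets; it lay between 19.5 and 30.8. Where both arrays of the dimmer group were at or below it, a fold is given as "at least N-fold": the brighter group's mean log2 value against the dim group's mean of, per array, the higher of the background and the probe set's own signal. No fold is given where both groups were at background.

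Probe sets were named from the platform annotation, with symbols updated by Entrez gene number through a RefSeq table of the Xenopus_laevis_v10.1 assembly, to which 15394 entries matched. Of the 32539 probe sets 15495 had a single symbol, 279 had several and were not named, and 16765 were unnamed; 11676 of those kept had a symbol, giving 8823 symbols. The suffixes .L and .S mark the copies of a gene on the long and short subgenomes, and closely related copies may cross-hybridise. No coordinates are given because the build behind the array design is not given in the sources used here. Probe sets for lrig1 and lrig2 were not analysed here. Probe sets of a named gene that were called in opposite directions were found for cyb561.L and lsf in the morpholino comparison, and neither is reported. Pax3.L is left out of the results too, because its brighter probe set was not called in the main fit where a dimmer one rose. In the morpholino comparison its probe set in the plate border list had a log2 change of -1.37. It did not pass in the main fit but passed with the replicate block (limma adjusted p = 0.00763).

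Before the data were examined, the design, the alternatives, 22 gene lists with at least 5 measured members and the rule for named genes were fixed. The lists cover neural crest, plate border, pan-neural, primary neuron, anterior neural and cement gland, midbrain to posterior neural, Wnt, BMP, FGF and retinoic acid genes, epidermis, secretory and mucus cells, multiciliated cells, ionocytes, mesoderm and muscle, dorsal mesoderm, endoderm, p53 and morpholino response, stress, cell cycle, maternal and housekeeping genes. Each symbol was represented by its brightest probe set. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 88 tests of 22 lists in 4 comparisons. Of these, 42 were called, and 1 with a correlation estimated from the residuals, the anterior neural and cement gland list for wnt3a; fry, which asks whether the genes of a list move on balance in a single direction without comparing them with other genes, called 36. Members were counted with the p-values adjusted over all probe sets and over the list alone. Named genes are, per comparison, the 10 largest rises and 10 largest falls among called probe sets whose groups did not overlap, up to 4 members of each list with the largest change, the injected messages and lrig genes, and up to 10 genes called for wnt3a and the morpholino in opposite directions and 5 in the same direction. Named outside this rule, and chosen after their values were seen, are snai2.L, rax.S, six6.L, sp5.L and axin2.S in the morpholino comparison, which the rule names for other comparisons, krt12.4.S and actc1.L as signals per array, and pou5f3.2.L, tdgf1.3.L and hes5.1.S in the closing section.

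The fit was tested on simulated data with the real means and spreads of the 22000 probe sets in the morpholino comparison, in 10 sets with 200 changed probe sets each. It recovered 16.5% of changes of log2 size 1, 70.8% of size 2 and 93.3% of size 4, and 7.66% of calls were false. In 20 simulations for the same comparison on 8823 genes, camera found a neural crest list shifted by -1 in all 20, and 34 of 420 tests of other lists fell under 0.05 unadjusted. Genes were drawn independently, each with the same spread in all groups. These simulations therefore do not test correlation between genes or spreads that differ between groups. The correlation and covariance expected from shared arrays came from 100 simulations with unchanged groups.

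Alternatives were quantile normalization, centring each array on its median, no pseudocount, a pseudocount 4 times larger, no filter, a stricter filter at the 60th percentile, eBayes without trend and robust, fits to only the 2 groups compared, the replicate number as a block, leaving out each array, a threshold of at least 2-fold, the mean of all probe sets per symbol, and camera with an estimated correlation or fry. Scaling to the 12 probe sets at the 3' end of the poly-A spike-in controls, matching tandem copies of list genes, list counts without morpholino replicate 1, and a split of the chordin and wnt3a arrays between the effects compared were added after the data were seen. Figures were drawn with matplotlib 3.10.9.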

Results

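Gene expression was measured in Xenopus laevis animal caps, the ectoderm at the animal pole of the blastula, which forms epidermis when it is cultured alone. Embryos were injected at the 2-cell stage, caps were cut at stage 9 and grown to stage 15, and labelled RNA was hybridised to 8 Affymetrix arrays. There were 4 groups of 2 arrays: uninjected caps, caps with chordin message, caps with chordin and wnt3a messages, and caps with both messages and an lrig3 morpholino. Chordin is a secreted antagonist of bone morphogenetic proteins (BMPs), Wnt3a is a secreted ligand of the Wnt pathway, and Lrig3 is a transmembrane protein with leucine-rich repeats and immunoglobulin-like domains. A morpholino is an antisense oligonucleotide that blocks translation or splicing of its target message. The study set out to find genes that depend on Lrig3 in caps given wnt3a and chordin.

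The arrays had median signals between 96.1 and 114, and between 68.6% and 76.0% of the 32539 probe sets lay above the background of their array. Arrays of the same group correlated at r = 0.929 to 0.967 across the 22000 probe sets kept for testing, and arrays of different groups at r = 0.739 to 0.925. These are correlations across probe sets, which are not independent replicates. With 2 arrays per group the number of arrays limits the precision. An exact two-sided permutation test of 2 arrays against 2 cannot go below p = 0.333, so no such test was run and every p-value below comes from the limma model. All changes are log2 differences of signal plus pseudocount, which understate the change of dim genes. Where every array of the dimmer group was at background, a fold is given as "at least" and is a lower bound set by that background.

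With chordin, 21 of 29 anterior neural and cement gland genes rose and 24 of 28 multiciliated cell genes fell. The eye-field genes rax and six6 were the clearest case: rax.S was at background in uninjected caps, with signals of 14 and 1, and reached 6199 and 4399 with chordin, at least 171-fold higher. The forebrain genes hesx1.S, vsx1.L and fezf2.L rose from background by at least 105-fold, 104-fold and 97.3-fold. Those that fell include the ciliary regulators foxj1.S, mcidas.S and ccno.S. The injected message was seen as chrd.1.S, which rose at least 19.8-fold from background (adjusted p = 5.93e-04).

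In the list of anterior neural and cement gland genes, 21 of 29 measured members rose and none fell; 23 rose and none fell when adjusted over the list alone. The median log2 change was 4.44, and the list stood apart from other genes (camera adjusted p = 1.15e-09, and adjusted p = 0.0600 with an estimated correlation). Six6.L rose by a log2 change of 8.07 (SE 0.70) and pax6.L, which acts in eye and forebrain, by 7.38 (SE 0.64). Of 25 pan-neural genes, 21 rose and 1 fell, or 21 and 2 adjusted over the list alone, with a median of 3.25 (camera adjusted p = 1.60e-08, and adjusted p = 0.346 with an estimated correlation). The zinc-finger gene zic2.L and the neural adhesion gene cdh2.L rose by 6.66 and 6.12, and zeb2.S and ncam1.S, which were at background in uninjected caps, at least 65.0-fold and 29.7-fold. Of 26 FGF pathway genes, 15 rose and 1 fell, 16 and 1 adjusted over the list alone, led by mycn.S at 4.66 and spry2.S, a feedback inhibitor of the pathway, at 4.22 (camera adjusted p = 5.49e-05, and adjusted p = 0.401 with an estimated correlation). Of 66 cell cycle genes, 31 rose and 3 fell, 33 and 3 adjusted over the list alone, with a median of 0.59 (camera adjusted p = 7.28e-06, and adjusted p = 0.401 with an estimated correlation). The replication genes mcm4.S and cdc6.S rose by 3.22 and 2.13, while the cyclin gene ccna1.S fell by 3.87 on the log2 scale. With any array of the 2 groups left out, limma called no cell cycle gene lower, and without uninjected replicate 1 or either chordin array no pan-neural gene; with the replicate block 2 pan-neural genes fell. Under spike-in scaling 40 cell cycle genes rose, and none of the cell cycle, pan-neural and FGF lists fell.

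Of 36 BMP target genes, 19 fell and 4 rose, or 23 and 5 adjusted over the list alone, with a mean of -1.88 (camera adjusted p = 5.15e-06, and adjusted p = 0.221 with an estimated correlation). The BMP feedback gene szl.S was 31.9-fold lower. Among those that rose, from background, was the BMP antagonist nog.L. Szl.L had a log2 change of -6.37 with an SE of 2.29 and did not pass (adjusted p = 0.0785). Of 28 multiciliated cell genes, 24 fell and none rose, 27 and 0 adjusted over the list alone, with a median of -3.65 (camera adjusted p = 1.54e-11, and adjusted p = 0.403 with an estimated correlation). Mcidas.S was at least 24.5-fold lower, ccno.S had a log2 change of -5.27 (SE 1.01) and foxj1.S one of -5.22 (SE 0.91). Of 32 epidermal genes, 13 fell and 2 rose, 15 and 3 adjusted over the list alone (camera adjusted p = 1.95e-04, and adjusted p = 0.496 with an estimated correlation). The basal regulator tp63.S had a log2 change of -3.54. Of 15 ionocyte genes only ca12.L, a carbonic anhydrase, passed over all genes, at -5.38 (adjusted p = 0.0673 with the replicate block), and none passed adjusted over the list alone, although the median was -4.32 (camera adjusted p = 0.00105, and adjusted p = 0.506 with an estimated correlation). The chordin arrays differed from each other in these genes: the ionocyte regulator foxi1.L had signals of 37.5 and 346 against 6511 and 5845 in uninjected caps. Of 7 endoderm genes, 5 fell and none rose, also adjusted over the list alone (camera adjusted p = 0.00470, and adjusted p = 0.403 with an estimated correlation). They include foxa1.L, at -4.16, and gata6.S, which are not restricted to endoderm. Without uninjected replicates 1 and 2 and chordin replicates 1 and 2, in that order, 6, 10, 8 and 17 multiciliated genes fell, 11, 12, 11 and 15 BMP targets, 3, 3, 4 and 5 epidermal genes, 2, 2, 2 and 3 endoderm genes and 0, 0, 0 and 0 ionocyte genes. Each left 1 epidermal gene higher, and the replicate block gave 4. Without either morpholino array 7 ionocyte genes fell, and 2 did with the block. Under spike-in scaling the counts higher and lower were 4 and 7 for epidermis, 6 and 15 for BMP targets and 0 and 0 for ionocytes, and 18 multiciliated genes fell.

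Camera called no other list in this comparison, while fry called the Wnt targets as higher (adjusted p = 0.0205) and the neural crest list as lower (adjusted p = 0.0393). Fry did not call the epidermal and ionocyte lists that camera called (fry adjusted p = 0.0893 and 0.114). In neural crest, 7 of 29 members rose and 7 fell, and 8 rose and 9 fell adjusted over the list alone. The transcription factor gene ets1.L was at least 22.9-fold lower. The plate border list had 10 of 23 members higher and 8 lower, and its median and mean, 0.15 and 0.87, were positive while the camera direction was down (adjusted p = 1.00). The counts higher and lower were 4 and 1 of 16 for primary neurons, 4 and 3 of 30 for posterior neural genes, 8 and 5 of 34 for Wnt targets, 4 and 4 of 14 for retinoic acid genes, and 2 and 2 of 8 for epidermal secretory genes, where the cement gland gene ag1.S rose by 3.35. Without uninjected replicates 1 and 2 and chordin replicates 1 and 2, in that order, 5, 3, 4 and 4 crest genes, 2, 1, 3 and 1 primary neuron genes, 2, 3, 2 and 2 retinoic acid genes and 2, 1, 1 and 1 secretory genes rose. In the same order 2, 5, 2 and 10 crest genes fell, 5, 5, 5 and 6 plate border genes, 1, 3, 1 and 4 Wnt targets, 0, 0, 2 and 0 primary neuron genes, 2, 3, 3 and 3 retinoic acid genes and 0, 0, 0 and 0 secretory genes. Posterior neural genes fell in 5 cases without either morpholino array and with the replicate block, under which 2 primary neuron genes fell. Under spike-in scaling the counts higher and lower were 10 and 7 for crest, 12 and 5 for plate border, 10 and 2 for Wnt targets and 5 and 3 for retinoic acid genes.

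Limma called 6445 of 22000 probe sets with the Benjamini-Hochberg adjusted p below 0.05, 3866 higher and 2579 lower. Scaled to the poly-A spike-in controls instead, a choice made after their signals were seen, the split was 6196 higher and 953 lower. The median of all probe sets moved from 0.09 to 0.62. The count was 2611 without uninjected replicate 1, 2956 without uninjected replicate 2, 2298 without chordin replicate 1 and 3545 without chordin replicate 2.

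**Figure D1:**
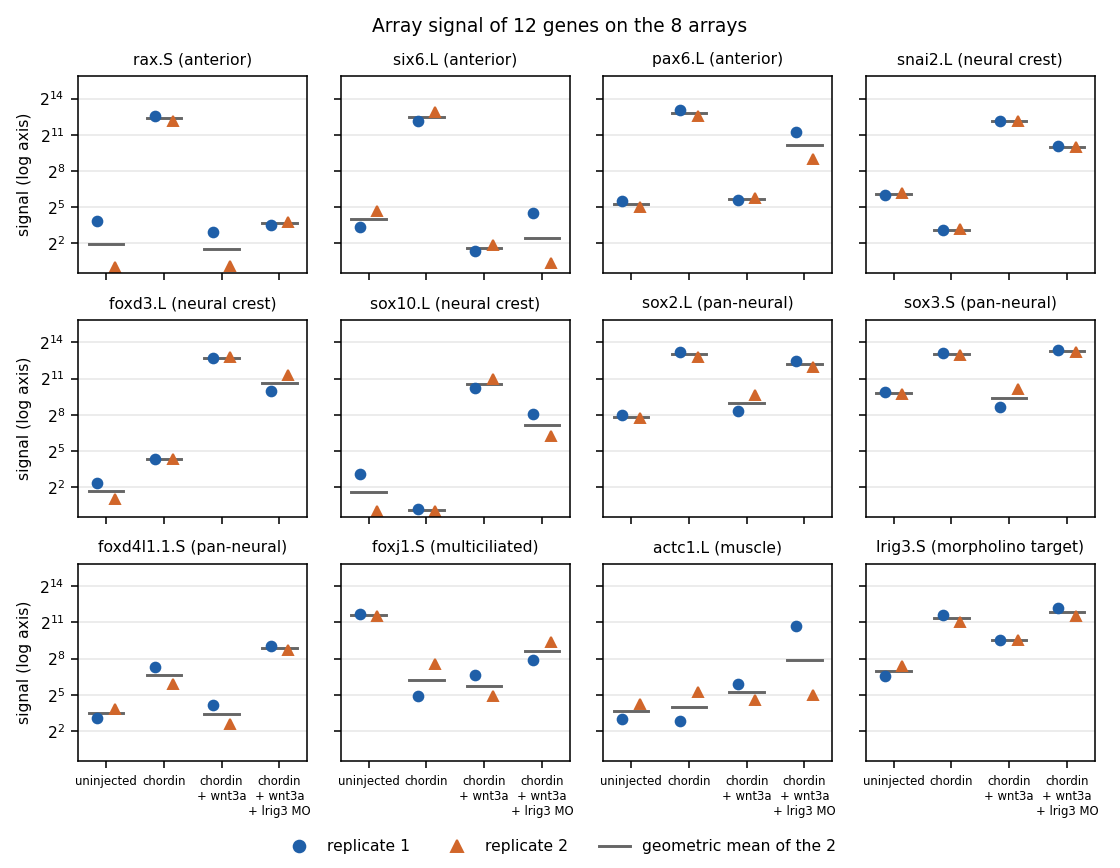
Array signal on a log axis, with values below 1 drawn at 1, for 12 genes on each of the 8 arrays; circles and triangles are replicates 1 and 2 and bars are the geometric mean of the 2. Rax.S is high with chordin alone, snai2.L is highest with chordin and wnt3a at 4602 and 4592, and actc1.L reaches 1709 on morpholino replicate 1 against 32.4 on replicate 2.

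With wnt3a added to chordin, 17 of 29 neural crest genes rose and 21 of 29 anterior neural and cement gland genes fell. Snai2.L, a neural crest regulator, rose from signals of 8.3 and 9.1 to 4602 and 4592, at least 171-fold. The crest genes foxd3.L and sox10.L rose at least 257-fold and 57.3-fold, and the plate border gene pax3.S at least 36.9-fold. The eye-field genes six6.L and rax.S returned to background, at least 207-fold and 185-fold lower. The injected message, read by wnt3a.S, rose at least 534-fold to signals of 10956 and 18771. The other injected message, read by chrd.1.S, had a log2 change of -1.78. It did not pass in the main fit but passed with the replicate block (limma adjusted p = 0.0461). Equal amounts of chordin message in these groups were therefore not shown.

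Of 29 neural crest genes, 17 rose and none fell, or 20 and 5 adjusted over the list alone, with a median log2 change of 4.16 (camera adjusted p = 1.45e-13, and adjusted p = 0.0600 with an estimated correlation). The log2 change of foxd3.S was 8.19 (SE 0.53). Of 23 plate border genes, 11 rose and 2 fell, 12 and 3 adjusted over the list alone, with msx2.L at 4.95 (camera adjusted p = 3.36e-06, and adjusted p = 0.109 with an estimated correlation). Both that fell are copies of hesx1, an anterior gene that the list also holds. Of 34 Wnt targets, 10 rose and 3 fell, 13 and 4 adjusted over the list alone, with a median of 0.83 (camera adjusted p = 3.84e-04, and adjusted p = 0.128 with an estimated correlation). They include sp5.L at 6.61 and the feedback genes axin2.S at 5.64 and kremen2.S, at least 22.0-fold. Of 30 midbrain, hindbrain and posterior neural genes, 4 rose and 4 fell, 9 and 4 adjusted over the list alone, with a median of 2.36 (camera adjusted p = 1.20e-04, and adjusted p = 0.496 with an estimated correlation). The hindbrain genes hoxb2.S, hoxa2.L and hoxa2.S rose at least 73.5-fold, 17.4-fold and 23.5-fold from background. The other riser was wnt3a.S itself, the injected message, which this list holds. Retinoic acid genes rose in 2 of 14 cases, 5 adjusted over the list alone, with cyp26a1.L, which degrades retinoic acid, at 2.73 (camera adjusted p = 5.95e-04, and adjusted p = 0.221 with an estimated correlation). Without chordin replicates 1 and 2 and chordin and wnt3a replicates 1 and 2, in that order, 8, 8, 9 and 7 plate border genes and 0, 1, 3 and 0 retinoic acid genes rose and 0, 0, 4 and 1 posterior neural genes fell. Without either morpholino array 8 posterior neural and 4 retinoic acid genes rose and 4 plate border genes fell, and with the replicate block 7 posterior neural genes rose.

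Of 29 anterior neural and cement gland genes, 21 fell and none rose, 25 and 1 adjusted over the list alone, with a median of -5.59. This list also passed with an estimated correlation (camera adjusted p = 6.13e-24, and adjusted p = 0.0248 with an estimated correlation). Besides six6.L and rax.S they include pax6.L, with a log2 change of -7.01. The pan-neural list split: 7 of 25 members fell and 4 rose, 12 and 6 adjusted over the list alone (camera adjusted p = 0.0310, direction down, adjusted p = 0.634 with an estimated correlation and adjusted p = 0.0616 with the replicate block). The neural progenitor genes sox2.L and sox3.S had log2 changes of -4.03 and -3.67, while irx1.L and zic4.L rose by 5.05 and 3.77. Of 66 cell cycle genes, 12 fell and none rose, 21 and 0 adjusted over the list alone, with cdc6.S at -2.03 (camera adjusted p = 2.07e-08, and adjusted p = 0.337 with an estimated correlation). Of 8 secretory and mucus genes, 4 fell and none rose, 5 and 1 adjusted over the list alone, the 4 being both copies each of agr2 and ag1, genes of the cement gland, with agr2.L at -7.97 (camera adjusted p = 7.45e-04, and adjusted p = 0.408 with an estimated correlation). Stress genes rose in 2 of 26 cases, among them hmox1.L by 1.14, and in 3 cases adjusted over the list alone (camera adjusted p = 0.00337, and adjusted p = 0.504 with an estimated correlation). The mesoderm and muscle list had 4 of 24 members higher and 2 lower, 6 and 2 adjusted over the list alone (camera adjusted p = 0.0310, and adjusted p = 0.403 with an estimated correlation). Its rises include wnt8a.L and pcdh8l.S, which encode a Wnt ligand and a protocadherin and rose at least 119-fold and 33.2-fold. Wnt8a.L also belongs to the Wnt target list and pcdh8l.S to the neural crest list, so these rises are not specific to mesoderm. The muscle gene actc1.L was not among the rises, with signals of 59.2 and 24.3. Without chordin replicates 1 and 2 and chordin and wnt3a replicates 1 and 2, in that order, 2, 4, 5 and 7 pan-neural genes fell, 3, 3, 6 and 6 cell cycle genes, 2, 2, 5 and 2 secretory genes and 1, 1, 1 and 1 mesoderm genes, while 2, 2, 4 and 2 pan-neural genes and 0, 1, 1 and 1 stress genes rose. Stress genes rose in 1 case without either uninjected array, mesoderm genes fell in 1 without either morpholino array, and with the replicate block 20 cell cycle genes fell. With the block agr2.S had an adjusted p of 0.0828. Under spike-in scaling 3 cell cycle genes fell and limma called no stress gene. Camera no longer called the pan-neural list without chordin replicate 1 (adjusted p = 0.145), nor the pan-neural, mesoderm and stress lists without chordin and wnt3a replicate 1 (adjusted p = 0.0697, 0.130 and 0.0954).

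Camera called no further list, while fry called the BMP targets as higher (adjusted p = 0.0343). Fry did not call the pan-neural, stress and secretory lists that camera called (fry adjusted p = 0.225, 0.254 and 0.0629). Counts higher and lower were 4 and 8 of 26 for FGF genes, with fgf8.L at -3.86, 4 and 2 of 32 for epidermis, 0 and 0 of 28 for multiciliated cells, and 0 and 1 of 15 for ionocytes. For BMP targets they were 7 and 2 of 36, and the median was -0.04 and the mean -0.01 while the camera direction was up (adjusted p = 0.320). Without chordin replicates 1 and 2 and chordin and wnt3a replicates 1 and 2, in that order, 1, 2, 4 and 2 FGF genes and 5, 6, 5 and 4 BMP targets rose, and 0, 1, 5 and 3 FGF genes, 2, 1, 4 and 1 BMP targets, 0, 1, 5 and 1 epidermal genes and 0, 0, 0 and 0 ionocyte genes fell. Without either morpholino array 4 BMP targets and 5 epidermal genes fell, and 1 multiciliated gene. Without either uninjected array 1 BMP target and no ionocyte gene fell by limma, and no ionocyte gene fell under spike-in scaling. Epidermal signals varied within the wnt3a group: the keratin krt12.4.S had signals of 10613 and 857.

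Limma called 1280 probe sets for wnt3a, 678 higher and 602 lower, at the Benjamini-Hochberg adjusted p below 0.05. The count was 449 without chordin replicate 1, 570 without chordin replicate 2 and 544 without chordin and wnt3a replicate 2. With the replicate block it was 2031, 1079 higher and 952 lower.

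The lrig3 morpholino was compared with caps that had the same messages without it. The target message itself, lrig3.S, was higher with the morpholino, with signals of 4787 and 3002 against 741 and 756 (log2 change 2.33, SE 0.35, adjusted p = 0.0246). A morpholino need not lower its message, so this does not measure the knockdown. Of 29 neural crest genes 10 fell, among them snai2.L, from 4602 and 4592 to 1046 and 1015, sox10.L by a log2 change of -3.35 (SE 0.67) and twist1.L by -3.21 (SE 0.47). Sox3.S, a gene of neural progenitors, rose from 391 and 1128 to 10335 and 9546, beside 8987 and 8044 with chordin alone. The anterior genes rax.S and six6.L were at background with and without the morpholino, while pax6.L rose by 4.33 (SE 0.64). The wnt3a.S signal was 27548 and 25480 against 10956 and 18771, a log2 change of 0.89 that did not pass (SE 0.35, adjusted p = 0.187), and chrd.1.S had a log2 change of -0.12 (SE 0.49).

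Of 29 neural crest genes, 10 fell and none rose, 16 and 0 adjusted over the list alone, with a median of -1.44 (camera adjusted p = 3.36e-06, and adjusted p = 0.128 with an estimated correlation). Besides sox10.L and twist1.L they included the protocadherin gene pcdh8l.S at -3.02 and ets1.S at -2.82. Given here because it led the wnt3a comparison, snai2.L had a log2 change of -2.15. Of 25 pan-neural genes, 9 rose and none fell, 11 and 0 adjusted over the list alone, with a median of 0.89 (camera adjusted p = 7.28e-06, and adjusted p = 0.403 with an estimated correlation). Under spike-in scaling the pan-neural median was -0.13, 5 rose and 4 fell, around a median of all probe sets of -0.95. The neural plate gene foxd4l1.1.S was at least 16.8-fold higher, and sox3.L and sox2.L rose by 3.34 and 3.24. Of 16 primary neuron genes 2 rose, also adjusted over the list alone: dll1.L, a Notch ligand, by 3.39 and isl1.S at least 1.62-fold (camera adjusted p = 0.00911, and adjusted p = 0.346 with an estimated correlation). The primary neuron median of 0.77 was -0.22 under spike-in scaling. Of 66 cell cycle genes 11 rose and none fell, 14 and 2 adjusted over the list alone, with cdc25b.L at 2.13 and wee2.L at 1.87 (camera adjusted p = 5.51e-05, and adjusted p = 0.403 with an estimated correlation). Under spike-in scaling 1 cell cycle gene rose and 28 fell, with a median of -0.79. Of 26 FGF genes 2 rose and 1 fell, also adjusted over the list alone: fgf3.L by 4.19 and fgf8.L by 3.07, while flrt3.L changed by -2.55 (camera adjusted p = 0.00105, and adjusted p = 0.403 with an estimated correlation). The FGF median of 0.61 was -0.39 under spike-in scaling. Of 10 maternal genes mos.L and zp2.L rose, by 1.29 and 1.12, and 3 rose adjusted over the list alone (camera adjusted p = 0.00845, and adjusted p = 0.403 with an estimated correlation). Spike-in scaling left none higher and 1 lower. Of 18 housekeeping genes ppia.L had a log2 change of -1.28, and 4 fell adjusted over the list alone (camera adjusted p = 0.0259, and adjusted p = 0.346 with an estimated correlation). Without replicates 1 and 2 of uninjected, chordin, chordin and wnt3a, and morpholino caps, in that order, limma called 5, 5, 5, 5, 0, 0, 0 and 5 crest genes lower, and 5, 7, 4, 4, 4, 3, 0 and 6 pan-neural, 6, 6, 5, 5, 1, 3, 0 and 5 cell cycle, 0, 0, 0, 1, 0, 0, 0 and 2 primary neuron, 1, 1, 1, 1, 1, 1, 0 and 4 FGF and 0, 0, 0, 0, 0, 0, 0 and 0 maternal genes higher. In the same order it called 1, 1, 0, 0, 0, 0, 0 and 1 FGF and 0, 0, 1, 1, 0, 0, 0 and 1 housekeeping genes lower. The crest median was -1.20 without morpholino replicate 1, and camera no longer called primary neuron and FGF genes (adjusted p = 0.108 and 0.208). The maternal call ended without chordin and wnt3a replicate 1 and without morpholino replicate 2 (adjusted p = 0.0752 and 0.0573), the housekeeping call without the latter (adjusted p = 0.0981). With the replicate block 18 cell cycle genes rose and 2 fell, and 5 housekeeping genes fell. Under spike-in scaling 22 crest and 17 housekeeping genes fell, and the counts higher and lower were 2 and 1 for primary neurons and 2 and 4 for FGF genes. With median centring 6 cell cycle genes rose and 1 fell, 1 maternal gene rose and 3 housekeeping genes fell.

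The morpholino replicates differed in genes of other tissues. Replicate 1 carried mesodermal and posterior signal: the muscle gene actc1.L had signals of 1709 and 32.4 on replicates 1 and 2, the mesodermal gene tbxt.L 1835 and 10.5, and hoxd10.L, a posterior gene, 2781 and 301. Replicate 2 carried epidermal cell types: foxj1.S had 235 and 647, the ionocyte gene ca12.L 24.8 and 899, and krt12.4.S 2161 and 18245. The posterior neural list was called as higher, with fgf8.L and pax2.L passing among its 30 members over all genes and over the list alone (camera adjusted p = 0.0110, and adjusted p = 0.666 with an estimated correlation). Its median of 1.06 became -0.41 without morpholino replicate 1 (camera adjusted p = 0.706), its call also ended without chordin and wnt3a replicate 2 (adjusted p = 0.0628), and limma called none of its genes when any array but morpholino replicate 2 was left out. The multiciliated list was also called as higher though none of its 28 members passed, even adjusted over the list alone (camera adjusted p = 2.67e-05, and adjusted p = 0.631 with an estimated correlation). Its median was 1.47, and 0.18 without morpholino replicate 2 (camera adjusted p = 0.191); with the replicate block 3 members rose. Under spike-in scaling the counts higher and lower were 1 and 1 for posterior neural and 0 and 1 for multiciliated genes.

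Camera called no other list, while fry called the Wnt targets as higher (adjusted p = 0.0370). Fry did not call the FGF, posterior neural and multiciliated lists that camera called (fry adjusted p = 0.0847, 0.426 and 0.265). Of 34 Wnt targets 2 rose and 1 fell: sp5l.S changed by 3.19 and sp5.L by -0.90, while axin2.S had a log2 change of 0.58 (adjusted p = 0.198). Of 31 p53 and morpholino-response genes 1 rose and 2 fell, 3 and 3 adjusted over the list alone, with tp53inp1.S at 1.92 and bax.S at -1.98 (camera adjusted p = 0.535), and of 26 stress genes 1 rose and 2 fell (camera adjusted p = 0.901). Of 36 BMP targets 1 rose and 2 fell, 6 and 2 adjusted over the list alone, the fallers being both copies of bmp2, with bmp2.L at -2.44. Of 14 retinoic acid genes rarg.S and dhrs3.L rose, by 1.31 and 1.49. The mesoderm list had 2 of 24 higher and 2 lower, plate border 1 of 23 higher, anterior 2 of 29 higher, and none passed among 32 epidermal, 15 ionocyte, 8 secretory, 13 dorsal mesoderm and 7 endoderm genes. In the epidermal list the median and mean were 0.04 and 0.01 while the camera direction was down. Without replicates 1 and 2 of uninjected, chordin, chordin and wnt3a, and morpholino caps, in that order, limma called higher 3, 3, 2, 2, 0, 1, 0 and 4 Wnt targets, 1, 1, 1, 2, 1, 1, 0 and 5 mesoderm, 0, 0, 1, 1, 0, 0, 0 and 1 retinoic acid, 0, 0, 0, 0, 0, 0, 0 and 1 anterior and 0, 0, 0, 0, 0, 0, 0 and 2 plate border genes. In the same order it called lower 0, 0, 0, 0, 0, 0, 0 and 0 Wnt targets, 2, 2, 2, 2, 0, 0, 0 and 2 mesoderm genes, 2, 2, 2, 2, 0, 0, 0 and 1 BMP targets, 2, 2, 2, 2, 0, 0, 0 and 2 p53 genes and 0, 0, 0, 1, 0, 0, 0 and 0 stress genes, and higher 1, 1, 1, 1, 0, 1, 0 and 1 BMP targets, 1, 1, 0, 0, 0, 0, 0 and 0 p53 genes and 0, 0, 0, 0, 0, 0, 0 and 0 stress genes. With the replicate block 5 Wnt targets, 5 BMP targets, 3 p53 genes and 2 stress genes rose and 4 mesoderm genes fell. Under spike-in scaling, around the median of all probe sets of -0.95, the counts higher and lower were 1 and 10 for Wnt targets, 0 and 11 for p53, 0 and 12 for stress, 0 and 10 for BMP targets, 0 and 5 for retinoic acid, 2 and 5 for mesoderm, 0 and 13 for plate border and 2 and 3 for anterior genes. Those lower were 13 epidermal, 1 ionocyte, 2 secretory, 1 dorsal mesoderm and 1 endoderm genes, with none higher.

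Limma called 1077 probe sets for the morpholino, 601 higher and 476 lower, at the Benjamini-Hochberg adjusted p below 0.05. With the replicate block the count was 3289, 1675 higher and 1614 lower. When only the 2 groups compared were fitted, it was 32. With each array centred on its median the split was 413 higher and 974 lower, and with spike-in scaling 182 higher and 9285 lower. The median of all probe sets moved from 0.03 to -0.13 with median centring and to -0.95 with spike-in scaling, and relative to it the neural crest median was -1.47 as deposited and -1.50 with spike-in scaling. The call count rested on every array: 0 without morpholino replicate 1, 462 without morpholino replicate 2, 50 and 31 without chordin and wnt3a replicates 1 and 2, 304 and 343 without chordin replicates 1 and 2, and 256 and 259 without uninjected replicates 1 and 2. Without morpholino replicate 1, limma gave 4035 probe sets at an unadjusted p under 0.05 and a lowest adjusted p of 0.0539.

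**Figure D2:**
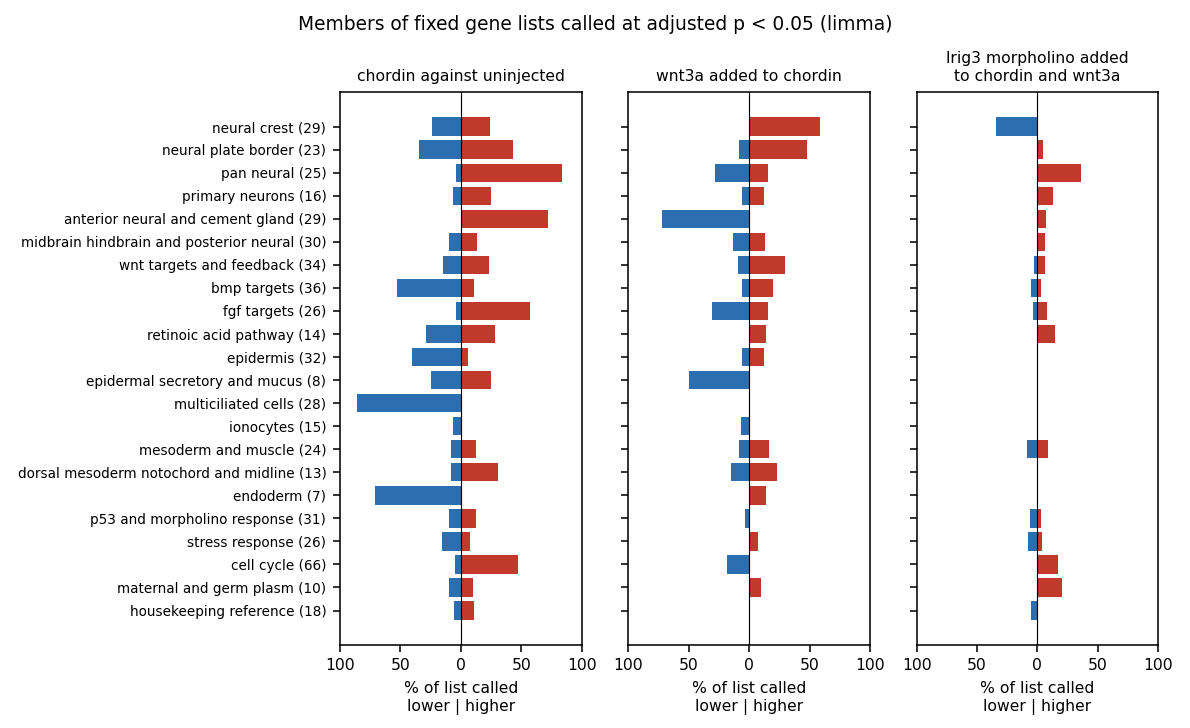
Share of the measured members of each fixed gene list, in percent, that limma called lower (bars to the left) or higher (bars to the right) in 3 comparisons; the number of measured genes stands after each name. Anterior neural genes go from 21 of 29 higher with chordin to 21 of 29 lower when wnt3a was added, and neural crest from 17 of 29 higher with wnt3a to 10 of 29 lower with the morpholino as deposited.

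The wnt3a and morpholino effects were set against each other to see which wnt3a-responsive genes the morpholino moved back. Genes called in both comparisons mostly moved in opposite directions: 97 probe sets raised by wnt3a were lowered by the morpholino and 105 lowered by wnt3a were raised, against 14.7 and 16.4 for independent lists. They include the crest genes sox10.L and twist1.L on one side and pax6.L, pcdh8.L, sox2.L, sox3.S and sox1.S on the other. Only 14 rose in both and 5 fell in both, where independent lists give 18.5 and 13.0; fgf3.L, wnt4.L and irx1.S rose in both, fgf3.L at least 2.87-fold and then by a log2 change of 4.19. Snai2.L had signals of 1046 and 1015 with the morpholino and of 8.3 and 9.1 with chordin alone, a difference that was not tested. The counts of probe sets called in both comparisons rest on the morpholino calls, which became fewer when any array was left out.

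The comparisons share the chordin and wnt3a arrays, which alone pushes the effects apart. Across the 22000 probe sets the correlation was r = -0.34, where groups without any change gave -0.50 in 100 simulations of independent arrays. The covariance was -0.235 against -0.118 from the shared arrays, a difference of -0.117. Of the wnt3a-raised probe sets 79.1% had a negative morpholino change, and 60.4% did in 20 simulations with no morpholino effect. Of those lowered, 79.9% had a positive change against 62.1%. With 1 chordin and wnt3a array used for each effect, so that no array was shared, the covariance was -0.103 and -0.124 in the 2 possible splits, a test added after the comparison was seen. Part of the excess in the overlap counts and in these percentages may come from the shared arrays. The difference in covariance was -0.0318 without chordin and wnt3a replicate 2 and -0.215 without replicate 1.

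**Figure D3:**
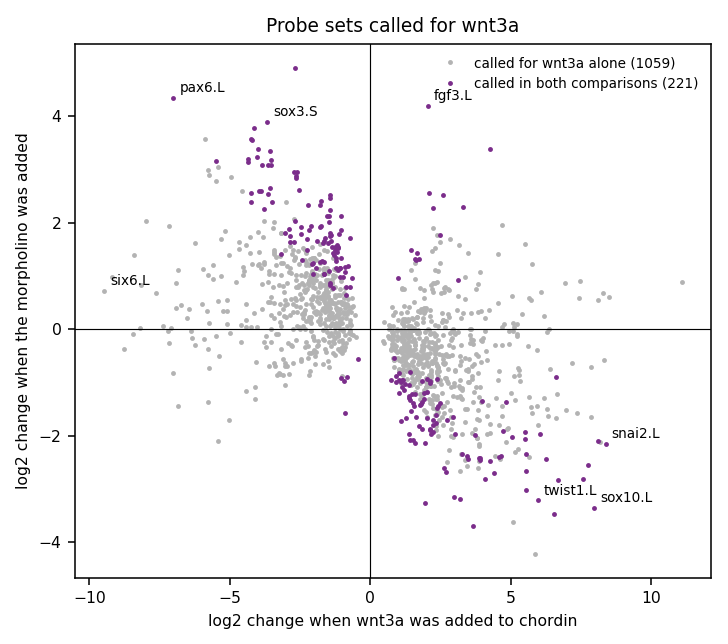
Log2 change on adding the morpholino (vertical) against log2 change on adding wnt3a (horizontal) for the 1280 probe sets called for wnt3a; purple points were called in both comparisons. Of these, 97 lie at lower right and 105 at upper left, and both axes share the chordin and wnt3a arrays.

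Against uninjected caps, chordin and wnt3a together raised 20 of 29 neural crest genes and lowered 27 of 28 multiciliated cell genes. Foxd3.L rose at least 225-fold, pax3.S at least 32.3-fold and the retinoic acid degrading enzyme gene cyp26c1.S at least 259-fold. Szl.L was at least 197-fold lower and tbx3.S had a log2 change of -7.42 (SE 1.52). Lrig3.S was 96.0 and 172 in uninjected caps, 3191 and 2158 with chordin (log2 change 4.30, SE 0.35, adjusted p = 7.74e-04) and 741 and 756 with both messages, lower than with chordin alone by a log2 change of -1.80 (SE 0.35, adjusted p = 0.0305) and higher than in uninjected caps by 2.50 (SE 0.35, adjusted p = 0.00370).

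Of 29 neural crest genes 20 rose and 4 fell, also adjusted over the list alone, with a median of 4.05 (camera adjusted p = 7.28e-06, and adjusted p = 0.128 with an estimated correlation); sox8.L rose by 6.72. Plate border genes rose in 16 of 23 cases and fell in 2, 16 and 4 adjusted over the list alone, with zic1.S at 7.01 (camera adjusted p = 6.63e-04, and adjusted p = 0.141 with an estimated correlation). Pan-neural genes rose in 18 of 25 cases, 20 adjusted over the list alone (camera adjusted p = 7.97e-08, and adjusted p = 0.346 with an estimated correlation). Wnt targets rose in 15 of 34 cases and none fell, 16 adjusted over the list alone (camera adjusted p = 4.41e-04, and adjusted p = 0.128 with an estimated correlation). FGF genes rose in 14 of 26 cases, 15 and 1 lower adjusted over the list alone (camera adjusted p = 8.12e-04, and adjusted p = 0.401 with an estimated correlation). Posterior neural genes rose in 8 of 30 and fell in 1, also adjusted over the list alone (camera adjusted p = 0.00989, and adjusted p = 0.666 with an estimated correlation). This list holds wnt3a.S, the injected message, so its values are not those of endogenous messages alone. Mesoderm and muscle genes rose in 7 of 24 cases and fell in 1, also adjusted over the list alone, led by wnt8a.L and the crest and mesoderm gene snai1.S at 4.34 (camera adjusted p = 0.0393, adjusted p = 0.403 with an estimated correlation and adjusted p = 0.0524 with the replicate block, under which 2 fell). The anterior list had 2 of 29 higher and 4 lower and was not called (camera adjusted p = 0.170). Camera no longer called the mesoderm and posterior neural lists without chordin and wnt3a replicate 1 (adjusted p = 0.0769 and 0.0692), nor the mesoderm list without uninjected replicate 2 (adjusted p = 0.0624). Fry alone called the retinoic acid and cell cycle lists as higher (adjusted p = 0.0205 and 0.0293). It did not call the posterior neural, epidermal, secretory and ionocyte lists that camera called (fry adjusted p = 0.0867, 0.140, 0.0548 and 0.0520). Without uninjected replicates 1 and 2 and chordin and wnt3a replicates 1 and 2, in that order, 9, 9, 10 and 8 FGF, 13, 11, 14 and 10 plate border, 4, 6, 6 and 4 posterior neural and 1, 2, 1 and 1 anterior genes rose, and 0, 0, 0 and 0 posterior neural and 0, 0, 6 and 0 anterior genes fell.

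Multiciliated genes fell in 27 of 28 cases, also adjusted over the list alone, with a median of -3.99 (camera adjusted p = 3.75e-12, and adjusted p = 0.403 with an estimated correlation). Ionocyte genes fell in 8 of 15, 11 adjusted over the list alone (camera adjusted p = 1.80e-04, and adjusted p = 0.466 with an estimated correlation). BMP targets fell in 17 of 36 cases and rose in 7, 20 and 7 adjusted over the list alone (camera adjusted p = 0.00276, and adjusted p = 0.401 with an estimated correlation). Epidermal genes fell in 11 of 32 and rose in 3, 14 and 5 adjusted over the list alone (camera adjusted p = 0.00313, and adjusted p = 0.631 with an estimated correlation). Endoderm genes fell in 6 of 7 cases and foxa2.L rose, also adjusted over the list alone (camera adjusted p = 0.0135, and adjusted p = 0.431 with an estimated correlation). Secretory genes fell in 4 of 8 cases, 5 adjusted over the list alone (camera adjusted p = 0.00470, and adjusted p = 0.496 with an estimated correlation). Without uninjected replicates 1 and 2 and chordin and wnt3a replicates 1 and 2, in that order, 14, 15, 25 and 11 multiciliated, 1, 0, 5 and 2 ionocyte, 5, 6, 15 and 7 epidermal, 1, 1, 5 and 1 secretory, 1, 4, 5 and 2 endoderm and 11, 14, 16 and 13 BMP target genes fell, and 0, 1, 2 and 0 epidermal genes rose. Ionocyte genes fell in 5 cases without either chordin array and with the replicate block, under which 6 epidermal genes rose. Under spike-in scaling the counts higher and lower were 6 and 6 for epidermis, 0 and 2 for ionocytes and 10 and 15 for BMP targets. Limma called 7414 probe sets, 4172 higher and 3242 lower, and with spike-in scaling 7165 higher and 1366 lower around a median of 0.69 in place of 0.11. At a threshold of at least 2-fold the split was 2530 higher and 2692 lower. The count was 3155 and 3669 without uninjected replicates 1 and 2, and 2926 without chordin and wnt3a replicate 2.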

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

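All tests in this part were chosen after the results they weigh had been seen. The poly-A control transcripts, which are added to each sample and were not used in the comparisons, had higher signals on the morpholino arrays than in uninjected caps, which is why they are listed here. Over 12 probe sets at their 3' ends the mean signal was 1609 and 1411 on the morpholino arrays, 1392 and 898 in uninjected caps, 807 and 719 with chordin, and 766 and 720 with chordin and wnt3a. Brighter arrays or the array scaling do not account for this, since the hybridization controls changed by a log2 value of 0.149 between the chordin and wnt3a arrays and the morpholino arrays while the poly-A controls changed by 1.02. Less messenger RNA per sample in morpholino caps remains possible but undecided, because the lower morpholino array lay 0.0192 above the highest other array on the log2 scale while the uninjected arrays differed by 0.633. No biological explanation was tested.

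Neural crest genes were lower in morpholino caps. Less injected wnt3a message would lower them and remains undecided: wnt3a.S differed by a log2 value of 0.885 (SE 0.352) on the deposited scale, which did not pass, and by -0.136 (SE 0.369) with the arrays scaled to the poly-A controls, which lowers all probe sets by a median of -0.953 and would be the right scale for a dose if messenger RNA was lower. Dilution by tissue without pan-neural genes would lower both lists alike. Instead, the mean change as deposited was -1.11 for the neural crest list and 1.26 for the pan-neural list. The difference was -2.37 (SE 0.390 over genes). The test cannot exclude such dilution together with a separate rise of pan-neural genes, which would give the same difference. The test cannot decide on dilution by neural tissue other than crest, because such tissue holds pan-neural genes itself. Replicate 1 alone did not carry the change. Without it 1 morpholino array was left, and the crest median was -1.20 (SE 0.308 over the genes of the list, not over arrays). What remains includes loss of Lrig3 and an effect of the morpholino on other messages, which could not be separated because no control morpholino was analysed here.

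Mesodermal genes were high on morpholino replicate 1. More wnt3a message on that array was not seen, with a log2 difference of 0.113 between the morpholino replicates against -0.777 between those of chordin and wnt3a. This compares 1 array with 1, so a small difference in dose could not be told from the spread between replicates. Mesodermal tissue carried into the caps or formed in them could not be decided by the test as written, which asked for most detected mesoderm and muscle genes: 19 of 41 were at least 4-fold higher on replicate 1, none was 4-fold lower, and 7 of the 19 were above background on both replicates of another group.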

How the results depend on the processing

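Spike-in scaling, the matching of tandem copies and the split of the chordin and wnt3a arrays were added after the data were seen. Call counts stayed within 1.5 times of the first count under quantile normalization, median centring, both pseudocounts, both filters, the plain variance model and the 2-fold threshold. The split did not: for the morpholino it was 413 higher and 974 lower with median centring against 601 and 476, and for both messages 2530 and 2692 at 2-fold against 4172 and 3242. For the morpholino, 32 probe sets were called when only the 2 groups compared were fitted. Such fits, with equally few degrees of freedom, called 6709 for chordin, 941 for wnt3a and 6366 for both messages. The cause of the loss for the morpholino was not tested. Under spike-in scaling, a shift of all probe sets by construction, 9467 were called for the morpholino. With the replicate block 8922 were called for chordin, 2031 for wnt3a, 3289 for the morpholino and 9799 for both messages. Under it 41 of 66 cell cycle genes rose with chordin, against 31 in the main fit. Of 29 crest genes 13 fell with the morpholino, against 10 in the main fit. The block ended 2 list calls, pan-neural for wnt3a and mesoderm for both messages, and changed no other list call. It kept 279 of the 284 calls for named genes and added 26. Leaving out each array, with the lone array assumed to vary like the other groups, gave 2298 to 6516 calls for chordin, 449 to 1358 for wnt3a, 0 to 462 for the morpholino and 2926 to 7417 for both messages. The covariance beyond shared arrays ranged from -0.215 to -0.0318, and the cause was not tested. Of 42 list calls, camera with an estimated correlation kept 1, fry 30, tandem matching 41 and leave-one-out 36 to 42. Of 284 calls among 390 values for named genes, leave-one-out kept 188 to 256 and spike-in scaling 250. Reversed values, all for the morpholino, were gmnn.S at -0.0120 under spike-in scaling and 2 lists, whose value is the mean change of their genes minus that of all other genes. These were the epidermis list, at -0.0554 in the first analysis, called higher at 0.416 without chordin and wnt3a replicate 1 (adjusted p = 0.0334), called lower at -0.527 without replicate 2 (adjusted p = 0.0106) and at 0.305 without morpholino replicate 1 (adjusted p = 0.406), and the posterior neural list, at 1.08 in the first analysis, at -0.331 without morpholino replicate 1 (2.49 without replicate 2), and the cause was not tested. Genes near the background of 19.5 to 30.8 have understated folds.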

Other observations

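Among further genes that were higher with the morpholino, pou5f3.2.L, tdgf1.3.L and hes5.1.S are named because their values stood out when seen. Pou5f3.3.L and pou5f3.2.L, relatives of the pluripotency gene Oct4, rose by log2 changes of 4.09 and 2.87, tdgf1.3.L, a Nodal co-receptor gene, by 3.70, and hes5.1.S, a Notch target, by 2.86. The signals of tdgf1.3.L were 918 and 604 with the morpholino and 51.1 and 54.0 without it.

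The test in this paragraph was chosen after the result was seen. Of 25 pan-neural genes 9 rose with the morpholino, among them sox2.L and sox3.S (5 rose and 4 fell under spike-in scaling), which a younger stage of those caps could produce together with higher maternal and cell cycle genes and lower primary neuron genes. The maternal list had a median log2 change of 0.917 and 11 of 66 cell cycle genes rose with none lower, as a younger stage would have it. Under spike-in scaling the maternal median was -0.00152 and the cell cycle median -0.787, around a median of all probe sets of -0.953. As deposited, the primary neuron list went against a younger stage, with a median of 0.766 (SE 0.258 over genes), 0.733 above the median of all probe sets. Its median was -0.221 under spike-in scaling (SE 0.265 over genes). That scaling keeps the distance to the median of all probe sets by construction, so it adds no support. The median was 0.662 without morpholino replicate 1. Relative to all probe sets the list was thus higher, where a younger stage was taken to lower it. This does not decide the question, because only 2 of 16 primary neuron genes passed and pan-neural genes rose as well. A difference in the amount of neural tissue was not separated from one in stage. Against the mean of uninjected caps, the list median was 1.35 and 0.372 on morpholino replicates 1 and 2. On chordin and wnt3a replicates 1 and 2 it was 0.586 and 0.0952, so morpholino replicate 2 lay between them.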
